A study of Mus musculus with 6 samples.

How the data were processed

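Polyadenylated RNA was sequenced from cells sorted by flow cytometry from the skin of mice that carry the diphtheria toxin (DT) receptor and eGFP at Lgr5. The sorted cells were positive for CD49f (integrin alpha 6) and CD34 and negative for GFP, which are hair follicle stem cells outside the reporter-positive population. The 6 libraries fall into 2 groups by the treatment named in the labels, saline and DT, with 3 libraries each. The labels give no replicate number, so libraries were numbered within a group in the order of their records, and equal numbers do not pair libraries.

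RNA was purified with the RNeasy Micro kit, with DNase treatment on the column, and its quality was assessed on a Bioanalyzer, per the labels' protocols. Reads were aligned with GSNAP to the mouse genome build GRCm38, per the submitters' processing notes. The version of the aligner and the gene annotation are not given in the sources used here, nor is whether counting used strand. The count of a gene is the number of reads that align uniquely to its gene model, per the file headers. The deposited files also hold an RPKM value, which the authors adjusted by a size factor of the library, per the file headers. Within each library this RPKM was an exact rescaling of the counts by the gene's length and 1 library factor, so the counts were used for the main test and the RPKM values for an alternative.

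Because reads with several alignments were left out, a gene with near-identical copies is under-counted, and genes that overlap share reads. Among the genes tested, 42 had the same counts in every library as another gene, and 11 of these passed the test. Gene identifiers were Entrez numbers. Symbols and coordinates came from the RefSeq annotation of GRCm38, which names 31049 of the 36528 listed identifiers, and 14371 of the genes tested.

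The libraries held 15300755 to 25558859 reads in genes, of which 98.2% to 98.5% fell in genes with a symbol. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15132. Library sizes were scaled by TMM, and DT was compared with saline by the robust quasi-likelihood test without covariates, at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are DT minus saline. Levels are CPM after TMM scaling, given as mean ± SD over the 3 libraries of a group. With 4 residual degrees of freedom and a biological coefficient of variation of 0.233, the test was tried on simulated counts for this comparison, with 200 changed genes among the 15132. It gave back 6.0% of changes of 1.5-fold, 35.8% of 2-fold changes and 75.8% of 4-fold changes, and called 5 unchanged genes. Far fewer genes were changed in the simulation than the 29.0% called in the data, and the adjusted threshold depends on that share. The simulated shares found are therefore not the power of the real comparison, though small changes could still be missed at this depth and number of libraries. In the same simulation 0 of 28 random lists passed the list test and a planted list of 33 genes did. Genes were simulated independently of each other, so this does not show how the test behaves for lists with correlated members.

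The 28 gene lists, the rule for named genes, the tests and the alternatives of the analysis, except those named as added, were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 28 lists, and again with an estimated correlation. Intervals of a list's median come from 2000 bootstrap draws of its members and cover 95%. For each list the members past the test are counted over all genes tested and adjusted over the list alone. Named genes were, in each direction, the 10 genes with the greatest absolute log2 fold change among those past the test, with a mean of at least 5 CPM in the higher group, all libraries of 1 group above all of the other, and a gene name (numbered predicted genes, clones and pseudogenes were left out). To these were added up to 4 members of each list with the smallest p, and Cd34, Itga6, Lgr5, Krt15, Krt14 and Hbegf. Other genes named in the text are the remaining members behind a small count, or were chosen after their values were seen. Some genes that the rule takes are counted in their lists but not reported here by name. Where every saline library was at 0, the fold is a lower bound against 3 counts over the 3 saline libraries, and bounds and counting intervals cover counting error only.

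The alternatives were the DESeq2 1.42.0 size factors, scaling by library size only, no filter on low counts, a filter on a mean count of 10, DESeq2 and limma-voom as tools, the number series of the submitters' sample identifiers as a block, consecutive identifiers as a pair, each library left out in turn, and an estimated correlation and fry for the lists. Added after the data were seen were limma on log2(RPKM + 1), a loess fit (span 0.5) that removed trends with gene length and GC content, and a fit of the larger identifier series alone. Other pseudocounts were meant for values without counts and were not run.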

Results

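The expression of genes was measured in CD49f-positive, CD34-positive, GFP-negative hair follicle stem cells of Lgr5-DTR-eGFP mice given saline or DT. In these mice Lgr5-expressing cells carry the receptor for diphtheria toxin, so that DT kills them, and the sorted cells are stem cells of the bulge without the reporter. Lgr5 was still at 24.1 CPM in the sorted saline cells, so some of them may have carried the receptor. Loss of such cells, or direct action of DT on them, cannot be told apart from a response of the other sorted cells. No group without the receptor was given DT. Each group had 3 libraries. Reads in genes came to 22741846, 21351548 and 22398109 in saline libraries 1 to 3 and to 22608451, 15300755 and 25558859 in DT libraries 1 to 3, with 17405 to 20994 genes detected. The dose of DT, the time between DT and collection and the stage of the hair cycle are not given in the labels. Nor do the labels say that libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. Xist and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had reads in all 6 libraries, with at least 289 for Xist and at least 123 for each Y-linked gene. Counts of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 21.9 to 66.6), so none was taken for a copy of another, which does not show that they were independent.

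The comparison asked how the remaining CD34-positive stem cells differed after Lgr5-expressing cells had been targeted with DT. All 34 cell cycle genes tested rose in the DT libraries, by a median of 10.5-fold (camera adjusted p = 1.26e-56, and adjusted p = 0.165 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, went from 9.62 ± 0.569 to 167 ± 64.3 CPM (SD, n = 3). Of 17 inflammatory genes 13 rose, including the adhesion molecule Icam1, from 12.7 ± 1.44 to 191 ± 25.7 CPM, and Cxcl1, a chemokine that attracts neutrophils, from 0.224 ± 0.167 to 158 ± 49.9 CPM. Of the bulge stem cell genes 10 of 19 fell and Krt14 rose (adjusted p = 0.311 with an estimated correlation). Falls were also seen for 6 of 8 Hedgehog pathway genes and 10 of 22 suprabasal epidermal genes (adjusted p = 0.17 and 0.17 with an estimated correlation). Lgr5 was at 24.1 ± 7.20 CPM in saline and 7.11 ± 0.143 CPM in DT. The level of Cd34, used for the sort, was 2804 ± 354.5 CPM in saline and 2348 ± 402.8 CPM in DT and did not pass the test.

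**Figure D1:**
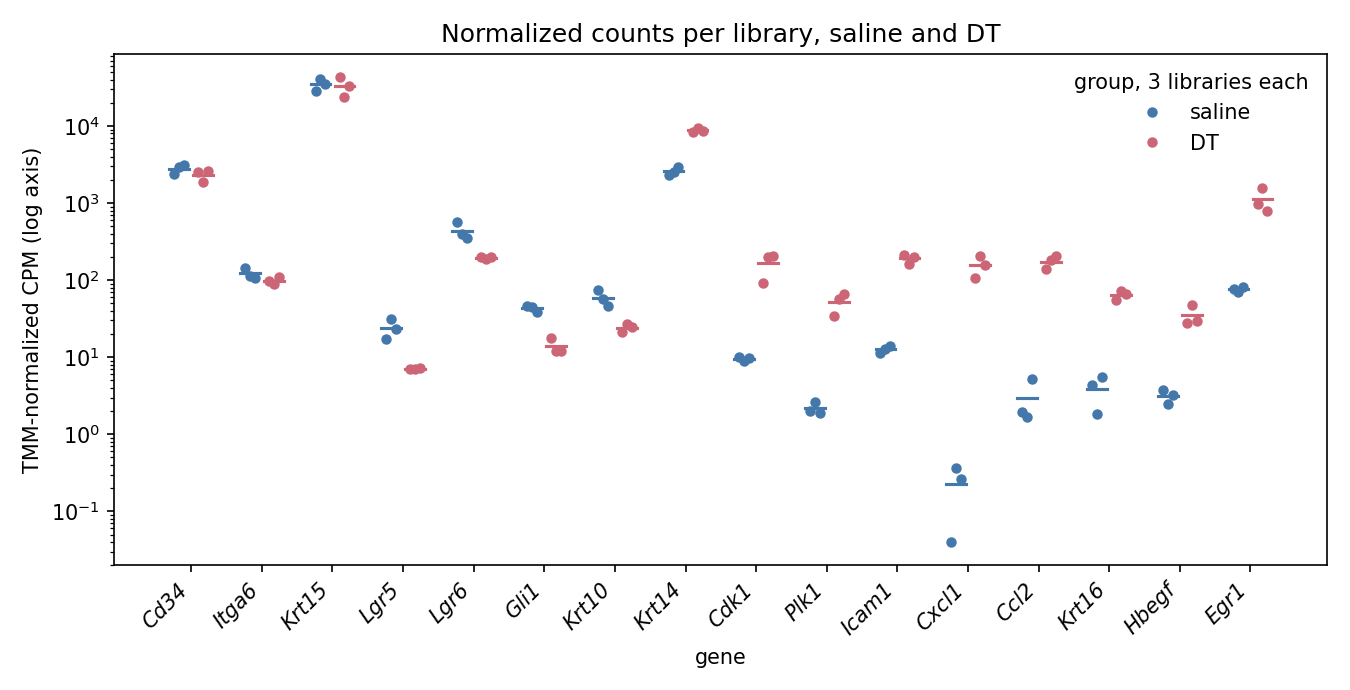
TMM-normalized CPM (log axis) of 16 genes in each library, with points for the 3 saline and 3 DT libraries and bars for group means. Cdk1 lay between 9.02 and 10.2 CPM in saline and between 92.5 and 207 CPM in DT, while the ranges of Cd34, Itga6 and Krt15 overlapped between groups.

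Of the 15132 genes tested, 2600 rose and 1795 fell in DT (29.0% of genes; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). More than 2-fold changes were found for 1326 genes that rose and 794 that fell, and more than 4-fold changes for 712 and 157. The 3 libraries of 1 group lay above all those of the other for 6941 genes (45.9%, where chance gives 10%), among them 4320 of the 4395 called. Of the called genes 59.2% were higher in DT, or 47.5% (2099 higher, 2316 lower) when scaled by library size only, which shifted the median log2 fold change of all genes by -0.098. The main axis of variation (67.0%) separated DT from saline, and the next (14.2%) set saline library 1, at 56.9, apart from saline libraries 2 and 3, at -30.7 and -34.5. Without saline library 1 the counts were 2381 higher and 1736 lower. Without saline library 2 the counts were 1849 higher and 1040 lower, without DT library 2 they were 1625 and 996, and without DT library 3 they were 1564 and 1017. The submitters' sample identifiers form 2 number series: within the larger, with 2 libraries per group, 1097 genes were higher and 473 lower, and the smaller held 1 library per group and allowed no test.

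Among the genes that identify the sorted cells, Itga6 (Entrez 16403, chromosome 2 from 71786886 to 71858427 in GRCm38), which encodes CD49f, was at 122 ± 20.5 CPM in saline and 98.8 ± 10.5 CPM in DT (log2 fold change -0.31, SE 0.15, adjusted p = 0.16). Cd34 (Entrez 12490, chromosome 1 from 194938821 to 194961292) had a log2 fold change of -0.26 (SE 0.16, adjusted p = 0.264). The bulge keratin Krt15 (Entrez 16665, chromosome 11 from 100131759 to 100135949), at 34810 ± 6583 and 33360 ± 9506 CPM, had one of -0.06 (SE 0.22, adjusted p = 0.854). Lgr5 (Entrez 14160, chromosome 10 from 115450314 to 115587780) fell by 1.76 on the log2 scale (SE 0.24, adjusted p = 0.000864). The basal keratin Krt14 (Entrez 16664, chromosome 11 from 100203162 to 100207510) rose from 2573 ± 331 to 8816 ± 513.5 CPM (log2 1.78, SE 0.14, adjusted p = 5.16e-05). Hbegf (Entrez 15200, chromosome 18 from 36504927 to 36515805), an EGF receptor ligand whose human ortholog is the toxin receptor, rose from 3.18 ± 0.641 to 35.1 ± 10.7 CPM (log2 3.46, SE 0.27, adjusted p = 4.72e-05). Reads of a human receptor transgene could not be told apart from those of mouse Hbegf in the counts. The receptor is carried at Lgr5, which fell in the same GFP-negative cells, and this argues against such reads as the source of the rise.

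All 34 cell cycle genes tested rose (34 adjusted over the list alone), with a median log2 fold change of 3.39 (interval 2.83 to 3.63; camera adjusted p = 1.26e-56, and adjusted p = 0.165 with an estimated correlation). The mitotic genes Ccnb2 (log2 4.61, adjusted p = 1.69e-05), Plk1 (4.59, adjusted p = 3.28e-05) and Cdca8 (3.63, adjusted p = 3.28e-05) had the smallest p-values of the list. Cdk1 (chromosome 10 from 69335146 to 69352912) rose by 4.11 (SE 0.30, adjusted p = 3.45e-05). Relative to the saline mean, the median of the list was 2.68, 3.58 and 3.74 in DT libraries 1 to 3 and -0.09 to 0.10 in the saline libraries. In the same libraries 10 of 17 immune cell markers fell and Itgam rose (median -0.92, camera adjusted p = 0.00383, and adjusted p = 0.311 with an estimated correlation). Of 5 smooth muscle, pericyte and skeletal muscle markers 3 rose (median 1.24, camera adjusted p = 0.016, and adjusted p = 0.17 with an estimated correlation, 0.159 with limma-voom and 0.0876 with limma on RPKM).

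Of 17 inflammatory genes linked to NF-kappaB, 13 rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 fold change of 1.71 (interval 1.40 to 6.14; camera adjusted p = 1.72e-23). This was the only list of the 28 past the test with an estimated correlation (adjusted p = 0.0107). Its median was also 1.71 with Cxcl2 and Tnf, at 0 counts in every saline library, set to their lower bounds. Icam1 (chromosome 9 from 21015940 to 21028814) rose by 3.91 (SE 0.17, adjusted p = 5.51e-06) and Cxcl1 (chromosome 5 from 90891245 to 90893121) by 9.45 (SE 0.43, adjusted p = 5.51e-06). Ccl2, a chemokine that attracts monocytes, rose by 5.89 (SE 0.39, adjusted p = 3.28e-05), or 6.58 without saline library 3. Cxcl2 was at least 248-fold higher. Of 17 immune cell markers 10 fell in the same libraries and the integrin Itgam rose (median -0.92, camera adjusted p = 0.00383, and adjusted p = 0.311 with an estimated correlation).

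Genes of wound-activated keratinocytes rose in 9 of 13 cases and fell in 0 (9 and 0 adjusted over the list alone). Their median stood at 2.22 (camera adjusted p = 7.53e-08, and adjusted p = 0.149 with an estimated correlation). Among them were the keratins Krt16 (log2 4.04, from 3.90 ± 1.86 to 64.6 ± 8.82 CPM), Krt6a (2.25) and Krt6b (2.22), and Inhba, the activin A subunit (4.46). Of 25 immediate early and dissociation stress genes, heat shock genes among them, 12 rose and 1 fell (14 and 1 adjusted over the list alone). The list median was 0.91 (camera adjusted p = 4.63e-06, and adjusted p = 0.195 with an estimated correlation). The transcription factors Egr1 (log2 3.87, from 76.6 ± 6.28 to 1119 ± 420.8 CPM), Jun (2.43) and Egr2 (1.93) rose, as did Zfp36 (1.36), which promotes the decay of cytokine mRNA. Klf4 fell (-0.63, adjusted p = 0.0078).

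Of 18 p53 target genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone). The median was 0.30 (camera adjusted p = 0.00112, and adjusted p = 0.165 with an estimated correlation). The cell cycle inhibitor Cdkn1a (log2 1.93), the pro-apoptotic Pmaip1 (4.74), Plk2 (2.28) and Eda2r (3.80) rose. Eda2r was at 0.443 ± 0.456 CPM in saline, and its log2 fold change was 3.18 without saline library 1 and 4.91 without saline library 3. In the unfolded protein and integrated stress response list, 9 of 20 genes rose and 1 fell (11 and 1 adjusted over the list alone). Their median stood at 0.62 (camera adjusted p = 0.000313, and adjusted p = 0.17 with an estimated correlation). Atf4, the central transcription factor of the integrated stress response, rose by 1.51. So did the serine synthesis enzyme Psat1 (2.32), the mitochondrial folate enzyme Mthfd2 (3.10) and the ER chaperone Hspa5 (1.11), and Herpud1 fell (-0.51, adjusted p = 0.014). Among 14 NRF2-linked antioxidant genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The list median was 0.63 (camera adjusted p = 0.0168, and adjusted p = 0.17 with an estimated correlation). Gpx2 (2.80), Hmox1 (2.13), which breaks down heme, and Osgin1 (2.33) rose, and the glutathione transferase Gstm1 fell (-1.03). Of 21 interferon-stimulated genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone). The median was 0.79 (camera adjusted p = 0.0184, and adjusted p = 0.515 with an estimated correlation). Cxcl10 (3.04), Gbp2 (1.74) and Ifit1 (1.61) rose, and Usp18 (-1.54) and Stat2 (-0.56, adjusted p = 0.0367) fell. The interferon list did not pass without DT library 1 (adjusted p = 0.184), nor with the trends of length and GC content removed (median 0.72, adjusted p = 0.0766). This removal also ended the call of the antioxidant list (median 0.55, adjusted p = 0.0791).

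Of 19 bulge stem cell genes, 10 fell and 1 rose (10 and 1 adjusted over the list alone). Their median stood at -0.56 (camera adjusted p = 0.00228, and adjusted p = 0.311 with an estimated correlation). The BMP antagonist Grem1 fell from 285 ± 57.7 to 104 ± 8.99 CPM (log2 -1.45, adjusted p = 0.000268). Lgr5 and Nfib (-0.66), a transcription factor of hair follicle stem cells, fell as well, and Krt14 was the gene that rose. The toxin receptor is carried at Lgr5, so the fall of Lgr5, counted here and among the Wnt genes, may follow from the targeting itself. Among 14 Wnt target and feedback genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone). The list median was -0.70 (camera adjusted p = 0.00486, and adjusted p = 0.168 with an estimated correlation). Wif1, a secreted Wnt inhibitor, fell from 768 ± 40.6 to 326.5 ± 79.5 CPM (log2 -1.24), and the ubiquitin ligase Rnf43 by 0.82 on the log2 scale, while Tcf7 rose (1.30). Lgr5, Sfrp1 (-0.94), Dkk3 (-0.72) and Znrf3 (-0.36) fell as well. The other 7 did not pass: Nkd1 (-1.99, adjusted p = 0.0988), Axin2 (-0.69, 0.107), Tnfrsf19 (-1.03, 0.11), Lef1 (-0.52, 0.358), Ccnd1 (0.23, 0.362), Apcdd1 (-0.28, 0.439) and Nkd2 (-0.44, 0.608). The Wnt list mixes target genes with inhibitors such as Wif1, so its median does not measure the output of that pathway. Of 8 Hedgehog pathway genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone). The median was -0.90 (camera adjusted p = 2.73e-05, and adjusted p = 0.17 with an estimated correlation). Gli1 (chromosome 10 from 127329882 to 127341579), a transcriptional readout of the pathway, fell from 43.3 ± 3.78 to 14.01 ± 3.47 CPM (log2 -1.62, SE 0.20, adjusted p = 0.00047). Other members that fell were Gli2 (-1.34), Ptch1 (-1.24), the co-receptor Gas1 (-1.03), the Hedgehog-binding inhibitor Hhip (-0.78) and Sox9 (-0.71). The list mixes target genes with receptors and co-receptors, so its median is not a measure of pathway output. In the same libraries 10 of 17 immune cell markers fell (median -0.92, camera adjusted p = 0.00383, and adjusted p = 0.311 with an estimated correlation). Of 8 fibroblast markers 3 fell, and their list, with a median of -0.90, did not pass (camera adjusted p = 0.0543).

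Lists of BMP and Notch signalling did not pass. Of 15 BMP and TGF-beta target genes, 1 rose and Ccn2 (log2 -0.91) and Ski (-0.67) fell (1 and 2 adjusted over the list alone). Their median was -0.10 and their mean 0.16, and the camera test, at adjusted p = 0.491, had the sign of the median. Ski did not pass without saline library 1 or 2 or DT library 2 or 3 (adjusted p up to 0.113). Of 9 genes of the Notch pathway, the ligand Jag1 fell (-0.57, adjusted p = 0.062 without DT library 3), or 3 fell and 1 rose adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.429).

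Suprabasal and cornifying epidermis genes fell in 10 of 22 cases and rose in 0 (13 and 0 adjusted over the list alone). Their median stood at -0.95 (camera adjusted p = 0.000139, and adjusted p = 0.17 with an estimated correlation). The suprabasal keratins Krt10 (log2 -1.30, from 59.5 ± 14.6 to 24.2 ± 2.63 CPM) and Krt77 (-1.42), the desmosomal Dsg1a (-1.12) and the protease Asprv1 (-0.90) fell. The other compartments did not pass as lists. Of 11 upper follicle genes, 6 fell and Klk10 rose (6 and 2 adjusted over the list alone; median -0.62, camera adjusted p = 0.0681), but the list passed without saline library 2 or 3 or DT library 3 (adjusted p down to 0.0266). Lgr6, a stem cell marker of the isthmus, fell from 435.9 ± 116 to 196 ± 4.62 CPM (log2 -1.16, adjusted p = 0.00151), and Krt79 fell by 1.37. Of 14 hair germ and matrix genes, Gata3 (-1.09), Pdgfa (-0.69) and Runx1 (-0.66) fell and 0 rose (2 and 0 adjusted over the list alone; median -0.47, camera adjusted p = 0.272). The adjusted p of Pdgfa reached 0.0564 without saline library 2 or DT library 3, and that of Runx1 0.148 without any library but saline library 3. Of 10 genes of the inner root sheath and hair shaft, S100a3 (1.39), Krt32 (1.25), Krt27 (1.65) and Krt73 (3.17) rose and Krt71 fell (-0.97), or 4 and 1 adjusted over the list alone (median 0.86, camera adjusted p = 0.0811). This list passed without any 1 saline library or without DT library 3 (adjusted p down to 0.0302). Krt73 had a log2 fold change of 2.56 without saline library 1 and 4.26 without saline library 3. Krt27 did not pass without saline library 2 or DT library 1 (adjusted p up to 0.0624), nor Krt73 without saline library 2, DT library 2 or DT library 3 (up to 0.109). Of 12 inner bulge and companion layer genes, Krt16, Krt6a, Krt6b and Timp3 (0.67) rose, and Krt79, Bmp6 (-2.30), Dkk3 (-0.72) and Sbsn (-0.52) fell, or 4 and 4 adjusted over the list alone (median 0.25, camera adjusted p = 0.21). Of 13 sebaceous gland genes, Acsbg1 (1.54) and Far2 (0.63) rose and Elovl4 (-0.83) and Mc5r (-2.17) fell, or 3 and 2 adjusted over the list alone (median -0.23, camera adjusted p = 0.479). Acsbg1 was at 305 CPM in DT library 1 and at 86.7 and 125 CPM in DT libraries 2 and 3, and its log2 fold change was 0.84 without DT library 1. The call of Far2 ended without saline library 1 or 2 or DT library 2 or 3 (adjusted p up to 0.12), and that of Mc5r without any library but saline library 1 (up to 0.107) or with consecutive identifiers as a pair block (0.0547). Of 20 genes of the basement membrane and hemidesmosome, 2 rose, among them the integrin subunit Itgb6 (1.11), and Npnt (-1.23), Col7a1 (-1.01), Egfl6 (-0.97), Col17a1 (-0.83) and Lama5 (-0.75) fell, or 2 and 5 adjusted over the list alone (median -0.31, camera adjusted p = 0.0681). The list passed without saline library 2 or 3 or DT library 1 or 3 (adjusted p down to 0.00795).

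Markers of other cell types were measured in the same libraries. Of 17 immune cell markers, 10 fell and 1 rose (11 and 1 adjusted over the list alone). The list median was -0.92 (camera adjusted p = 0.00383, and adjusted p = 0.311 with an estimated correlation). The T cell receptor subunit Cd3g (log2 -1.75) and the antigen presentation genes Cd74 (-0.64) and H2-Aa (-0.81, adjusted p = 0.0515 without DT library 3) fell. Itgam, found on myeloid cells, rose from 0.344 ± 0.301 to 4.03 ± 2.17 CPM (3.54, adjusted p = 0.0638 without DT library 2, and log2 2.92 without saline library 1). Of 5 smooth muscle, pericyte and skeletal muscle markers, Acta2 (6.34, from 0.867 ± 0.264 to 71.1 ± 42.1 CPM), Cnn1 (4.17) and Tagln (1.24), all genes of contractile actin fibres, rose and 0 fell (3 and 0 adjusted over the list alone), while Ckm of skeletal muscle, at -0.79, did not pass. The median of the 5 was 1.24 (camera adjusted p = 0.016, and adjusted p = 0.17 with an estimated correlation), and the list did not pass with limma-voom (adjusted p = 0.159) or with limma on RPKM (adjusted p = 0.0876). The median was 0.51 without saline library 2 and 0.61 without DT library 3. Tagln did not pass without saline library 1 or 2 or DT library 2 or 3 (adjusted p up to 0.141). Of 8 fibroblast markers, Col5a1 (-2.07), Col1a2 (-1.22) and Fbln1 (-0.94) fell and 0 rose, or 3 and 0 adjusted over the list alone (median -0.90, camera adjusted p = 0.0543), and the list passed without saline library 2 or 3 or DT library 3 (adjusted p down to 0.0251). Of 5 melanocyte markers, Dct (-2.86), Tyrp1 (-2.83) and Mitf (-0.62) fell and Gpnmb rose (1.69), or 3 and 1 adjusted over the list alone (median -0.62, camera adjusted p = 0.216). The melanocyte median was -1.73 without saline library 1, where the list passed (adjusted p = 0.0271), and -1.24 and -1.64 without DT library 1 or 2, where it did not. The log2 fold change of Tyrp1 was -2.24 without DT library 1. Without saline library 2 or 3 or DT library 2 neither Mitf (adjusted p up to 0.0711) nor Tyrp1 (up to 0.12) passed, and Tyrp1 did not pass without DT library 3 (adjusted p = 0.0785) or with consecutive identifiers as a pair block (0.0532). Of 6 Merkel and Schwann cell markers, the simple epithelial keratins Krt18 (5.53) and Krt8 (1.98) rose and 0 fell, or 2 and 0 adjusted over the list alone. The median of this list was -0.46 but its mean 0.73, whose sign the camera test shared (adjusted p = 0.555). Krt18 had a log2 fold change of 4.91 without saline library 1 and 6.36 without saline library 2. None of 9 endothelial, 2 mast cell or 6 erythrocyte and adipocyte markers passed, over all genes or adjusted over the list alone. The medians of these lists were -0.60, -0.78 and -1.14 (camera adjusted p = 0.386, 0.914 and 0.161). Hbb-bs and Hbb-b1 had the same counts in every library, and with 1 of them the last median was -1.05. Over all 6 it was -0.48 without DT library 1, and the list passed without saline library 2 (adjusted p = 0.0439).

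**Figure D2:**
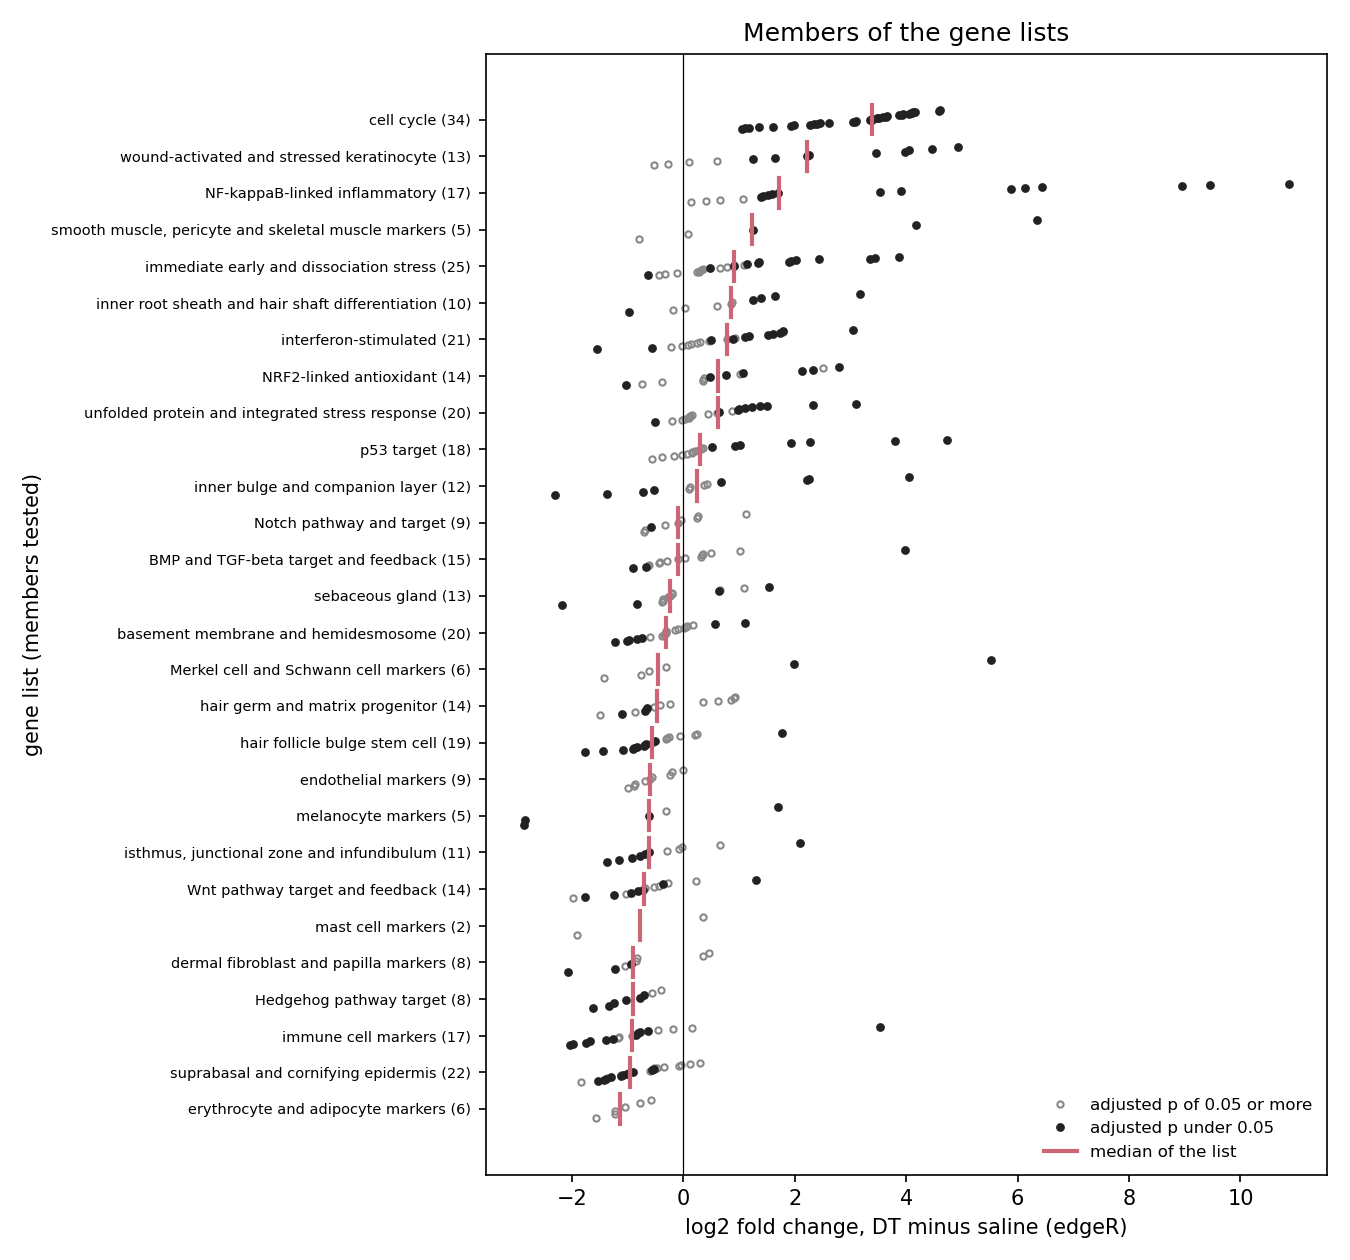
Log2 fold change, DT minus saline, of each member of the 28 gene lists, with filled points for members past the edgeR test, open points for the others and a bar at the median of each list. All 34 cell cycle genes lie to the right of 0, and the 22 suprabasal epidermis genes have a median of -0.95.

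Among single genes, those with the greatest rise were at or near 0 in saline. Nppb, a natriuretic peptide gene, had 0 counts in the saline libraries and 16.1 ± 8.84 CPM in DT, at least 368-fold higher. By the same bound Il18rap, a subunit of the interleukin 18 receptor, was at least 356-fold higher, and the protease inhibitor Serpinb1b at least 236-fold. The noncoding Mirt1 was at least 158-fold higher and Ptcra, a subunit of the receptor of immature T cells, at least 119-fold. Il23a, a subunit of interleukin 23, had 1 count in saline and 614 in DT, a depth-adjusted ratio of 689 (95% counting interval 123 to 27300). Fcer2a, the low-affinity IgE receptor, had 1 and 363, a ratio of 408 (72.7 to 16100). Hfm1, a helicase gene, rose from 0.168 ± 0.220 to 37.1 ± 24.7 CPM (log2 7.79), or by 7.18, 9.58 and 7.07 on the log2 scale without saline library 1, saline library 2 or DT library 2. The single saline counts of Il23a and Fcer2a lay in saline libraries 3 and 2. The greatest falls were those of Cnksr2 (log2 -3.56, or -2.95 and -4.16 without DT library 1 or 2) and Grik1 (-3.50), which encodes a glutamate receptor subunit and went from 111.5 ± 13.3 to 9.76 ± 4.50 CPM. The transcription factor Ebf1 fell from 31.7 ± 5.39 to 3.90 ± 0.904 CPM (-3.01), and Dct, Ctsw (-2.56), Skint6 (-2.55, or -3.50 without DT library 3), Ucn2 (-2.48) and Akr1c14 (-2.45) fell as well. The gene models of the microRNA hairpins Mir23b (-3.35) and Mir27b (-2.42) overlap longer transcripts, so the source of their reads is uncertain.

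Of the 126 named genes, 104 were called, and 79 of these were called under every alternative tried. With the trends of length and GC content removed, calls ended for Rnf43 (log2 -0.53, adjusted p = 0.058), Col17a1 (-0.44, 0.117), Runx1 (-0.45, 0.158), Ski (-0.34, 0.271) and Tagln (1.14, 0.0576). Without a low-count filter those of Acsbg1 (adjusted p = 0.151), Mc5r (0.0625) and Tyrp1 (0.0516) ended, and with limma on RPKM those of Mc5r (0.063), Runx1 (0.0886) and Ski (0.0619). Those of Ccn2, Cd3g, Cd74, Cst6 (log2 -0.78), Ctsw, Krt8, Mir27b and Nfib ended only within the larger identifier series (adjusted p from 0.0636 to 0.133).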

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

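The removal of trends with length and GC content, limma on log2(RPKM + 1) and the fit of the larger identifier series were chosen after the data were seen, and the other alternatives before. Genes higher in DT numbered 2600, and 2099 to 3595 under the other scalings, filters, tools and blocks. Genes lower in DT numbered 1795, and 2957 with limma-voom, or 1102 with the trends of length and GC content removed, where 13086 genes, 1578 of the lower calls among them, had both values. There 2781 of the 3883 calls with both values (71.6%) were kept and 9 changed sign. With the larger identifier series alone, which has 4 libraries, genes higher in DT were 1097 and genes lower in DT 473. With each library left out in turn, genes higher in DT ranged from 1564 to 2826 and genes lower in DT from 996 to 2045. Fewer libraries entered each of these fits, yet without DT library 1 both counts, 2826 and 2045, lay above those of the full fit. Gene lists higher in DT numbered 9 and gene lists lower in DT 5. With an estimated correlation, gene lists higher in DT were 1 and gene lists lower in DT 0, and fry, which does not compare a list with other genes, gave 18 in all. Gene lists lower in DT were 8 without a low-count filter, 8 in the larger identifier series and 5 to 9 with each library left out. The cause of these shifts was not tested.

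Of the 104 called named genes, none changed direction under any alternative and 25 lost the call in at least 1. The direction of 5 named genes that did not pass was reversed in places: the log2 fold change of Egfl7 was 0.24 with limma-voom, the log2 fold change of Cdh5 was 0.028 and the log2 fold change of Esam was 0.285 in the larger identifier series. Over single libraries left out, the log2 fold change of Hdc ranged from -0.022 to 0.895, the log2 fold change of Krt15 from -0.29 to 0.096, and the log2 fold change of Esam from -0.915 to 0.33. The cause was not tested. Deviations from the group means did not clearly pair the libraries. For consecutive identifiers their correlations across genes were 0.016, 0.013 and 0.165, and for the other combinations of saline and DT -0.138 to 0.089. The highest was that of saline library 3 with DT library 3, so a pairing of these stays open. The pair block called 2703 genes higher and 1889 lower. At 15300755 reads DT library 2 was the shallowest, and simulated changes of 1.5-fold were mostly missed (6.0% found).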

Other observations

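The added lists and the tests described here, apart from the splits of the libraries, were chosen after the data were seen, the length and GC test and that of the opposite clock arm before their own results. Genes of the contractile actin cytoskeleton rose in 13 of 17 cases and fell in 0, with a median log2 fold change of 1.14 (camera adjusted p = 5.2e-12 over the added lists, and adjusted p = 0.188 with an estimated correlation). The tropomyosins Tpm1 (2.17) and Tpm2 (1.66) and the myosin light chain Myl9 (2.89) rose. The list was made after Acta2, Cnn1 and Tagln had been seen to rise, and without these 3 genes, which the smooth muscle list also holds, 10 of 14 rose (median 0.88, camera adjusted p = 2.23e-09, and adjusted p = 0.132 with an estimated correlation). Ribosome biogenesis genes rose in 15 of 23 cases and fell in 0 (median 0.67, camera adjusted p = 8.86e-06, and adjusted p = 0.33 with an estimated correlation), among them Nop58 (1.49) and Ncl (1.17). Cholesterol synthesis genes rose in 9 of 18 cases and fell in 0 (median 0.75, camera adjusted p = 0.0021, and adjusted p = 0.33 with an estimated correlation), with Sc5d at 1.48 and Sqle at 1.43. Of 5 EGF receptor ligands, Epgn (4.29) and Hbegf rose and Btc fell (-1.21), with a median of 1.88 (-1.21 to 4.29; camera adjusted p = 0.00264, and adjusted p = 0.248 with an estimated correlation). This list was made after Hbegf had been seen to rise, and without Hbegf it did not pass (median 1.06, camera adjusted p = 0.118). Of 15 glycolysis genes, 5 rose, among them Eno1 (0.88) and Pgk1 (1.19), and Hk2 fell (-0.96), and the list did not pass (median 0.32, camera adjusted p = 0.118). The nuclear noncoding RNA Malat1 fell from 7850 ± 3102 to 1666 ± 8.34 CPM (-2.24, adjusted p = 0.000237).

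Reads of Xist, transcribed from the inactive X chromosome of females, and of Y-linked genes occurred together in all 6 libraries. Xist had 289 to 1545 reads and Ddx3y 1102 to 2163. Xist was lower in DT (log2 -0.98, adjusted p = 0.0143), while the Y-linked genes Ddx3y (0.58), Kdm5d (-0.24), Eif2s3y (-0.12) and Uty (0.09) did not pass.

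For the rise of all 34 cell cycle genes, immune cells as a whole in the gate are argued against by their 17 markers, with a median log2 fold change of -0.92 (-1.39 to -0.64), and Cd74, an abundant one, fell from 152 ± 20.6 to 98.0 ± 9.47 CPM. The marker list did not pass with an estimated correlation (adjusted p = 0.311). Its member Itgam rose (3.54), so a rare immune type stays open. Of 9 endothelial (median -0.60, -0.89 to -0.20) and 8 fibroblast markers (-0.90, -1.22 to 0.36), 0 rose past the test. This argues against a greater share of these cells in DT as the source. Neither list passed, however, and the endothelial Eng, Egfl7, Cdh5 and Esam stood at only 0.368 to 2.96 CPM in DT. Other types stay open, although a gate for CD34 and CD49f would remove cells that lack either. The list of 2 mast cell markers (median -0.78, -1.92 to 0.36) did not pass. Acta2 (6.34), Cnn1 (4.17) and Tagln (1.24) of smooth muscle and Krt18 (5.53) and Krt8 (1.98) of Merkel cells rose. A trend with gene length and GC content is argued against as the whole cause, since the median of the list was 3.39 (2.62 to 3.64) after its removal. Hair germ and matrix cells in the gate cannot be told apart from proliferating bulge cells, because the 14 markers went both ways around a median of -0.47 (-0.68 to 0.61), although the gate would remove hair germ cells that lack CD34 or carry Lgr5-eGFP. As to chance, 1 of the 10 splits of the 6 libraries, the real one, gave 4395 genes and the highest of the others gave 0, but 10 splits are too few for a share under 0.1.

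The rise of inflammatory and immediate early genes may reflect the response to DT, dissociation of the tissue, or immune cells in the gate. Immune cells as a whole are argued against by their 17 markers, with a median of -0.92 (-1.39 to -0.64), though the list did not pass with an estimated correlation (adjusted p = 0.311). Itgam, Il18rap, Fcer2a and Ptcra, which immune cells use, rose, so a rare type that these markers miss stays open. Stress of dissociation stays open: the 8 heat shock genes, which it also induces and of which Hspa1a, Hspa1b, Hsph1 and Dnajb1 belong to the immediate early list itself, had a median of 0.34 (-0.33 to 0.77), with Hspa8 (0.77), Hspe1 (0.81) and Hspd1 (0.64) past the test and Hspa1a (-0.44) and Hspa1b (-0.33) not.

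Clock genes went both ways. After Per3 (-2.02) and Bhlhe41 (-1.90) had been seen to fall, a shift of clock phase between groups was considered. The test assumed that the opposite arm of Arntl (Bmal1) would then rise together. Members of an arm need not peak at the same hour, so a shift could also move them in different directions. Arntl (2.11) and Cry1 (1.58) rose, but Clock (-0.17), Nfil3 (-0.29) and Npas2 (-1.17, adjusted p = 0.0511) did not pass, and the median of the 5 was -0.17 (-1.16 to 2.11), which decides nothing. Within the Per3 arm Tef (-0.97) and Per2 (-0.87) also fell while Ciart (2.30), Nr1d1 (1.69), Dbp (1.06) and Nr1d2 (0.73) rose, so that 4 of 10 fell and 4 rose (camera adjusted p = 0.118). The hour of collection is not in the labels, and a difference in hour cannot be told apart from an effect of DT.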
